A study of Mus musculus with 70 samples.

How the data were processed

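Gene expression was measured in mouse dorsal root ganglia (DRGs), the clusters of sensory neuron cell bodies beside the spinal cord. The animals came from 9 strains, named here by their labels 129, AJ, C3H, C57, CAST, DBA, NOD, NZO and WSB. Per the labels, each sample held total RNA from 6 DRGs of 3 mice, either uninjured (naive) or injured by axotomy, the cutting of the neurons' axons. The injured samples carry the label AX5D, read here as 5 days after axotomy. The labels describe the replicates as biologically distinct, so the spread between replicates is a spread between pools of mice. RNA was turned into biotinylated cRNA with an Illumina kit and hybridised to Illumina arrays, per the labels.

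The deposited table gives an intensity for each of 25697 probes on each of 72 arrays. A p-value (detection) stands beside each intensity, per the file headers. The intensities lay between 164 and 53947, with array medians between 253 and 392, on a linear scale with no sign of background subtraction or normalization. The software behind both quantities is not given in the sources used here. The authors also deposited a matrix of log2 values, from 7.64 to 15.50. Set against the intensities, that matrix was the log2 of quantile-normalized intensities without background correction, with a largest difference of 0.027 and a rank correlation of 1 on every array. Of the 72 arrays, 2 of strain AJ, which the series design calls technical outliers, belong to no labelled sample and were not used in any step. The other 70 arrays formed 18 groups of strain and treatment, 16 groups of 4 replicates and 2 groups of 3, both of AJ.

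Intensities were background-corrected from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. Background correction stretches differences of weakly expressed genes, and quantile normalization assumes that arrays share 1 distribution of values. A probe was kept if its detection p-value was below 0.05 on at least 3 arrays, which left 17616 probes, 16568 of them with a gene symbol. Where a gene had several kept probes (3261 genes), the probe with the highest mean was used, which left 11815 genes. Between 13147 and 14721 probes per array were above background. An array has no read depth, and the number of arrays limits the precision of each value.

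For each gene limma fitted 1 mean per group, with moderated variances that followed the mean level (residual degrees of freedom 52, prior degrees of freedom 8.60). The comparisons were axotomy against naive as a mean over the 9 strains and in each strain, the response of each strain against the mean response of the other 8, CAST against the mean of the other 8 strains after axotomy and in naive ganglia, and moderated F-tests with 8 degrees of freedom for a strain difference in the response or in the naive level. All p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and all adjusted p-values for genes come from limma. Levels are given as mean ± SD over arrays, and differences with their standard error (SE). A gene that was not above background on any array of a group has only a lower bound for its fold.

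In all, 28 gene lists were tested in 4 comparisons with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, with p-values adjusted over the lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list moves in 1 direction on balance. The lists cover regeneration-associated genes, activin and other TGF-beta signalling, neuron types, channels, glia, immune and other cell types, and general cell functions. Members were also adjusted over the list alone. Skeletal muscle and large-diameter neuron markers share Pvalb. Responses of strains were compared by correlations across genes, and genes are not independent replicates.

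The groups, comparisons, lists, most alternatives and the rule for named genes were set before the data were examined. The rule named Inhba, Atf3, Jun, Sox11, Sprr1a, Gap43, Gal and Npy in every comparison, and up to 8 genes with the highest and 8 with the lowest log2 difference among those past the threshold with the same sign in each strain or against each strain. It also named up to 3 members of each list with the smallest adjusted p, the 5 genes with the smallest p in each F-test and all measured activin members. No kept probe with a symbol measured Sox11. Genes outside the rule were chosen after their values were seen.

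Alternatives were the authors' matrix, no background correction, median scaling, 3 other filters, all probes in place of 1 per gene, array weights, arrays of a strain alone, blocks by replicate number, a fold of at least 1.5, and leaving out each strain and each array. After the data were seen, runs of 8 neighbouring columns were found to resemble each other. The mean correlation of residuals was 0.14 within the 9 runs and −0.03 between them. A block for these runs and leaving out runs 4 and 9 were then added. The fits were tested on simulated data with 11815 genes and the same groups. For the response of CAST against the other 8 strains, 41.8% of genes changed 1.5-fold were recovered, 82.1% at 2-fold and 100% at 4-fold. With no change, 0 of 112 list tests with camera were called, but the simulated genes varied independently, so correlation within lists was not tested. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15, and version 1.17.8 of the R package data.table read the tables. No genome was used, so probe sequences were not compared with the strains' genomes.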

Results

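Ganglia of all 9 strains were compared before and 5 days after axotomy, with 35 naive and 35 axotomy arrays. The genes named first are the 8 with the highest and the 8 with the lowest change among those selected for the same sign in each strain. Npy, neuropeptide Y, rose by 7.37 on the log2 scale (SE 0.09, 165-fold) as a mean over the 9 strains. The transcription factor Atf3, a standard marker of injured neurons, rose by 5.56 (SE 0.06, 47.2-fold). The other genes of the highest 8 were the peptidase gene Ecel1 (6.02, SE 0.06), the cholecystokinin receptor Cckbr (5.97, SE 0.05), the small proline-rich protein gene Sprr1a (5.76, SE 0.11), the serotonin transporter Slc6a4 (5.68, SE 0.06), Wfdc3 (5.61, SE 0.06) and the receptor Gpr151 (5.52, SE 0.05). The neuropeptide gene Gal (galanin) rose by 4.67, the transcription factor gene Jun by 1.45 and Gap43, a growth cone protein gene, by 1.35. The lowest 8 were Vstm2b (−1.89, SE 0.06), the serotonin receptor subunits Htr3b (−1.89, SE 0.08) and Htr3a (−1.83, SE 0.07), Igsf21 (−1.82), Rem2 (−1.73), Lin7b (−1.72), the itch receptor gene Mrgprb5 (−1.69, SE 0.10) and Glb1l2 (−1.66). In all, 7291 of 11815 genes (61.7%) passed adjusted p 0.05, 3320 higher and 3971 lower, of which 109 rose and 0 fell at least 4-fold. Slc6a4 was above background on 1 of 35 naive arrays, Cckbr on 5 and Ecel1 on 8, so their folds depend on where background lies.

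Regeneration-associated genes rose as a group: 29 of 31 measured members were higher and 1 was lower, with a median of 1.91 (adjusted p 3.2e-26, camera). Gadd45a, a stress-response gene, rose by 2.90. Macrophage markers were higher in all 19 members as means over the 9 strains (median 2.13, adjusted p 1.8e-19), among them the complement genes C1qc (2.84) and C1qb (2.82) and the mannose receptor Mrc1 (2.25). Of these 19, Ly86 (mean 0.24) was below 0 in 5 strains, and Fcer1g (0.57) was above background in CAST and C57 alone. All 11 complement and acute phase genes were higher (median 0.49, adjusted p 2.3e-05), with C4b at 1.38, Serpina3n at 0.49 and Cd59a at 0.47. Cell cycle genes were higher in 11 of 15 members, 12 when adjusted over the list alone (median 0.54, or 0.47 with the gene not above background at its bound, adjusted p 0.00018), with Prc1 at 2.69, Mcm6 at 1.15 and Cenpa at 0.83. Cholesterol synthesis genes were higher in 9 of 16 and lower in 2 (median 0.14, adjusted p 0.00886), led by Hsd17b7 (1.86), Mvd (0.64) and Sqle (0.31).

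Other groups rose under camera's preset correlation but not with an estimated one. Genes of MHC and antigen presentation were higher in 15 of 18 members (median 0.60, adjusted p 2.5e-05, adjusted p = 0.0599 with an estimated correlation), with Cd74 at 1.47, H2-Ab1 at 1.41 and B2m at 0.74. Interferon-stimulated genes were higher in 17 of 20, 18 when adjusted over the list alone (median 0.73, adjusted p 7.7e-07, adjusted p = 0.0858 with an estimated correlation), with Igtp and Usp18 both at 1.53 and Oas2 at 1.34. Without CAST the interferon median was 0.41. Fibroblast genes were higher in 12 of 14 (median 0.56, adjusted p 0.00024, adjusted p = 0.106 with an estimated correlation), among them the matrix genes Lum (1.03), Col1a1 (0.81) and Col5a1 (0.66). Neutrophil markers were higher in all 11 (median 0.87, adjusted p 0.009, adjusted p = 0.493 with an estimated correlation), with Retnlg at 1.09, S100a8 at 1.00 and Csf3r at 0.86. Immediate early genes were higher in 7 of 10 (median 0.44, adjusted p 0.00336, adjusted p = 0.0954 with an estimated correlation), with Arc at 0.78, Dusp1 at 0.69 and Junb at 0.53.

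Genes of mature sensory neurons fell. The list of voltage-gated channels was lower in 20 of 23 members and higher in 2 (median −0.76, adjusted p 2.1e-09, camera). It includes the potassium channel gene Kcna2 at −1.23 and the sodium channel subunit Scn4b at −0.76. The list also held Kcnk1 (−0.96), a potassium leak channel gene that is not voltage-gated. Large-diameter neuron markers were lower in 9 of 11, 10 when adjusted over the list alone, and higher in 1 (median −0.47, adjusted p 0.000424). They include the transcription factor Etv1 (−1.24), Whrn (−1.08) and the calcium-binding protein gene Pvalb (−0.76). Nociceptor markers were lower in 12 of 16 and higher in 2 (median −0.49, adjusted p 0.00281, adjusted p = 0.0838 with an estimated correlation). Mrgprd fell by 1.56 and the sodium channel Scn11a by 0.81, while Gfra3, the receptor of the growth factor artemin, rose by 1.49. Oxidative phosphorylation genes were lower in 15 of 21 (median −0.10, adjusted p 0.0214, adjusted p = 0.098 with an estimated correlation), and with median scaling the call was lost (adjusted p 0.055). Ndufs3 was at −0.37, Uqcrc1 at −0.25 and Uqcrc2 at −0.22, and 1 member was higher when adjusted over the list alone.

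The remaining lists did not pass camera. Axon growth inhibition genes were lower in 11 of 19 and higher in 4 (median −0.16, or −0.13 with 2 genes at their bound, adjusted p 0.126), with the myelin protein gene Omg at −1.41, the Nogo receptor homologue Rtn4rl1 at −1.12 and Lingo1 at −0.69. TGF-beta and BMP signalling had 7 members higher and 11 lower of 21 (median −0.22, mean −0.01, adjusted p 0.985), and fry put the list upward (adjusted p 1.1e-06). Tgfbi was at 1.48, Tgfb1 at 1.44 and Tgfbr1 at 0.83. Satellite glia markers had 3 higher and 4 lower of 13 (median −0.03, adjusted p 0.887), with the filament gene Gfap at 0.71, Ednrb at 0.18 and S100b at −0.90. Myelinating Schwann cell markers had 9 higher and 1 lower of 18 (median 0.08, adjusted p 0.126), with Arhgef19 at 0.75, Gldn at 0.62 and Pmp2 at 0.51. Cytosolic ribosome genes had 8 higher and 1 lower of 13 (median 0.14, adjusted p 0.0802), with Rps2 at 0.39, and without a filter the list passed (adjusted p 0.0343).

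Among cell types that a dissected ganglion can carry along, T and NK cell markers had 3 of 11 higher (median 0.05, adjusted p 0.459), with the chemokine Ccl5 at 1.502. The median was 0 with 2 of these genes at their bound. B cell markers had 2 of 5 higher and 1 lower (median 0.05, adjusted p 0.459), with Fcmr at 2.62 (above background on 5 of 35 naive arrays) and Cd79a at −0.54. Endothelium and pericyte genes had 1 of 16 higher and 2 lower (median −0.03, adjusted p 0.985, with camera's direction upward), 1 of them when adjusted over the list alone, and Vwf at 0.44. Skeletal muscle genes had 2 of 15 lower (median −0.08, adjusted p 0.519), with Eno3 at −0.65. Adipocyte genes had 1 of 6 higher, Car3 at 2.54 (median −0.09, mean 0.36, adjusted p 0.731, with camera's direction upward). Erythroid genes had 1 of 5 lower, Car2 at −0.43 (median 0.06, adjusted p 0.887, with camera's direction downward). Markers of CNS oligodendrocytes had 1 of 3 higher, Cldn11 at 0.42 (median 0.05, adjusted p 0.666). Sex-linked transcripts had 2 of 4 lower, Kdm5d at −0.28 and Uty at −0.25 (median −0.17, adjusted p 0.666). With a block for runs the call of Kdm5d was lost (adjusted p 0.0971), as were both without runs 4 and 9 (adjusted p 0.248 and 0.11). In total camera called 15 of 28 lists, 11 up and 4 down, of which 8 held with an estimated correlation, and fry called 24.

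Activin is a secreted dimer of Inhba or Inhbb subunits that signals through type 2 and type 1 receptors and the Smad proteins, and follistatin (Fst) binds and blocks it. As a mean over the 9 strains, Fst rose by 4.12 (SE 0.07), Inhbb by 2.69 (SE 0.08), the receptor gene Acvr1c by 1.98 (SE 0.06), Acvr1 by 1.11 and Inhba by 0.91 (SE 0.08, 1.88-fold, adjusted p 3.3e-16). Smad2 (0.31), Tgfbr3 (0.22) and Smad4 (0.22) were also higher. Fstl1 (−0.53), Inha, the subunit of inhibin (−0.36), and the type 2 receptor genes Acvr2a (−0.27) and Acvr2b (−0.11) were lower, and Smad3 was at −0.03 (adjusted p 0.755). The list passed camera (8 of 13 higher, 4 lower, median 0.22, adjusted p 0.00336). Inhba was above background on 26 of 35 axotomy arrays and 4 of 35 naive arrays, and Acvr1c on 35 and 2. The call of Acvr2a was lost with a block for runs (adjusted p 0.301). That of Acvr2b was lost without any single one of 14 arrays (highest adjusted p 0.0659) and without strain NOD (adjusted p 0.131).

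Axotomy changed many genes in each strain. The count of genes past adjusted p 0.05 was 2270 in AJ, 2795 in C57, 2939 in NOD, 3211 in C3H, 3240 in NZO, 3608 in CAST, 3756 in 129, 3955 in DBA and 4443 in WSB. In NZO 1700 genes were higher and 1540 lower, and with median scaling 1699 and 962. Altogether 544 genes were higher and 488 lower in all 9 strains, 2176 genes passed in exactly 1 strain, and 227 passed in opposite directions in different strains. Of the genes called in the mean over strains, 4128 (56.6%) had the same sign in all 9. Across genes, which are not independent replicates, the responses of the 36 pairs of strains had a mean Pearson correlation of 0.79 (0.68 to 0.87) and a mean Spearman correlation of 0.65. The slope of a strain's response on the mean of the others ran from 0.86 in AJ and C57 to 1.23 in WSB.

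Single genes separated the strains after axotomy. Sprr2f, a small proline-rich protein gene, rose at least 7.24-fold in NOD and 6.20-fold in WSB and was not above background on any array of the other strains. Klk4, a kallikrein protease gene, rose at least 6.80-fold in CAST and was not above background on any array elsewhere. The lipase gene Lipn rose at least 13.1-fold (129) to 31.9-fold (WSB) in the other 8 strains and was not above background on any CAST array. A probe that binds CAST poorly would also give no signal there, which was not tested. Cstdc4 rose at least 24.8-fold in DBA, 21.1-fold in C3H, 17.2-fold in C57 and 11.0-fold in CAST. In WSB it rose by 4.28 on the log2 scale. Its rise was at least 1.505-fold in AJ, 1.22-fold in NOD and 1.17-fold in NZO, and in 129 it was above background on 1 array. Cstdc4 was above background on 1 naive array, of WSB, and Sprr2f, Klk4 and Lipn on no naive array. Ly86, a macrophage surface protein gene, rose by 2.67 in WSB, 0.99 in C3H and 0.82 in AJ and fell by 0.78 in CAST, 0.70 in 129, 0.48 in C57 and 0.28 in DBA, while NOD (−0.20) and NZO (0.11) did not pass. The strains where Ly86 rose had its lowest naive levels, 7.43 in WSB, 9.61 in C3H and 10.02 in AJ. Elsewhere these were 11.97 (NZO) to 13.32 (C57). The rises thus came where the naive signal of the probe was lowest, and probe sequences were not checked. Sprr2f, Klk4, Lipn, Cstdc4 and Ly86 are the 5 genes with the smallest p among the 1915 (16.2%) whose response differed between strains in the F-test, a count that fell to 1224 with median scaling. The response of CAST differed from the mean of the other 8 in 948 genes and that of WSB in 811. The counts for the other strains were 418 for 129, 305 for NZO, 294 for DBA, 165 for AJ, 141 for C57, 131 for C3H and 107 for NOD. With median scaling the counts were 633 for CAST, 451 for WSB, 263 for NZO, 205 for 129 and 71 (NOD) to 179 (DBA) for the rest. AJ has 3 replicates where the other strains have 4. Of the 131 genes of C3H, 78 were higher and 53 lower, and with median scaling 59 and 24.

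**Figure D1:**
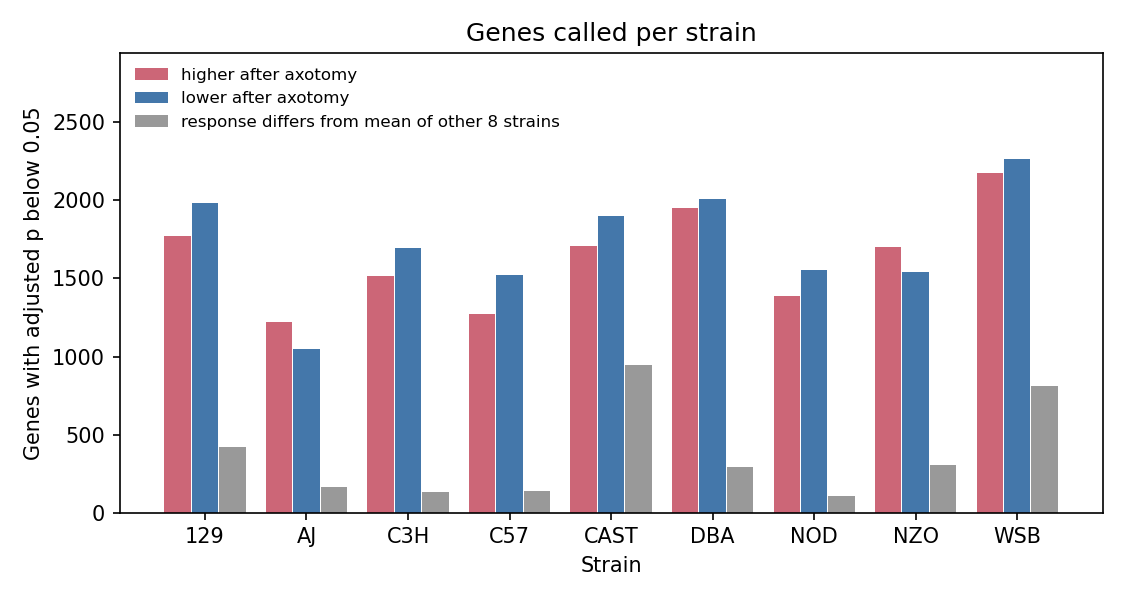
Number of genes (vertical axis) with adjusted p below 0.05 in each strain (horizontal axis). Red and blue bars count genes higher and lower 5 days after axotomy than in naive ganglia, and grey bars count genes whose response differed from the mean of the other 8 strains, with CAST (948) and WSB (811) highest.

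Inhba rose more in CAST than in the other strains. Its level in CAST went from 6.11 ± 0.54 (SD, n = 4) in naive ganglia to 9.27 ± 0.37 (n = 4) after axotomy on the log2 scale, a rise of 3.15 (8.90-fold, adjusted p 3.8e-18, limma). The mean response of the other 8 strains was 0.63, and the response of CAST exceeded it by 2.52 (SE 0.25, adjusted p 2.1e-12). The excess ran from 2.02 against DBA to 2.84 against 129. As Inhba was not above background on any naive array of these strains, both values depend on where background lies. After axotomy CAST was higher than the mean of the other strains by 3.15 (SE 0.17, 8.87-fold, adjusted p 1.6e-24) and than each strain by 2.70 (DBA) to 3.54 (129). In naive ganglia it was higher by 0.63 (adjusted p 0.0021), a call lost without CAST naive replicate 2 (adjusted p 0.092) and without runs 4 and 9 (adjusted p 0.142). Within the 4 runs that held CAST arrays after axotomy, CAST minus the other strains was 2.50 to 3.52. Naive CAST arrays lay in other runs, where the same difference among naive arrays was 0.15 to 1.14. Without background correction the response difference was 1.301, the level difference after axotomy 1.47, that in naive ganglia 0.17 and the mean response of the 9 strains 0.31, all past the threshold. Counted from the most positive value, Inhba ranked number 15 of 11815 genes for the response difference and number 23 for the level difference after axotomy.

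Inhba also rose in DBA (1.13, at least 1.52-fold, adjusted p 5.6e-05, limma) and WSB (0.77, at least 1.17-fold, adjusted p 0.00549). The rises in C3H (0.71), NOD (0.65, at least 1.16-fold) and NZO (0.66, too close to background for a bound) passed as well, with adjusted p 0.0146, 0.0288 and 0.0248. Without background correction these 3 were lost (adjusted p 0.0674, 0.0712 and 0.0565). A block for runs ended the call in C3H (adjusted p 0.0932) and NZO (0.0903), leaving out runs 4 and 9 that in C3H (0.201), median scaling that in NZO (0.0885), and a fit to the strain's own arrays that in NOD (0.066). Leaving out 1 of 8 arrays ended the call in C3H (2 arrays, highest adjusted p 0.0689), NOD (3 arrays, 0.193) and NZO (3 arrays, 0.0792). In AJ (0.45), C57 (0.36) and 129 (0.31) Inhba did not pass (adjusted p 0.263, 0.295 and 0.344). It was not above background on any naive array of 129, C57, DBA, NOD, NZO or WSB, and was on 2 of 4 in CAST.

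**Figure D2:**
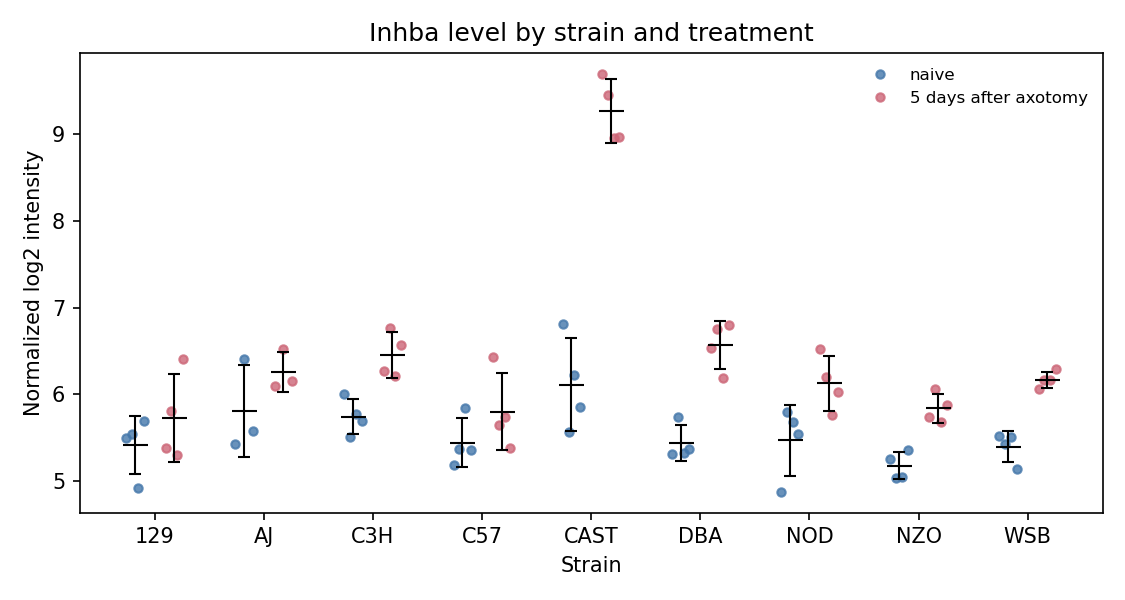
Inhba level (vertical axis, normalized log2 intensity) in each array (points) by strain (horizontal axis), naive in blue and 5 days after axotomy in red; bars show mean ± SD. The 4 CAST axotomy arrays average 9.27 and the DBA ones, the next highest, 6.57.

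Among the other activin genes, Fst rose less in CAST, by 2.24 against 4.35 in the others (difference −2.12, SE 0.23, adjusted p 6e-11), from a naive level that was 1.55 higher in CAST. Fst was above background on 24 of 35 naive arrays, so the size of its difference depends on where background lies. For Acvr1c the response difference was −1.30 (SE 0.20, adjusted p 1.5e-06), but as the gene was above background on 2 of 35 naive arrays the rises themselves are mostly lower bounds, at least 1.16-fold in CAST. Inhbb differed by 0.55 (adjusted p 0.171), and camera did not call the list (1 member higher, 2 lower, adjusted p 0.935). After axotomy Inhbb (0.69), Acvr2b (0.53) and Acvr1 (0.36) were higher in CAST than in the other strains, and Acvr1c (−1.27) and Inha (−0.84) were lower. Inha was also lower in naive ganglia (−0.76). The level of Fst after axotomy was lower by −0.56, a call lost without CAST axotomy replicate 4 (adjusted p 0.0579). Smad3 (0.47), Smad2 (0.20), Fstl1 (−0.17) and Tgfbr3 (−0.19) passed there too, each lost without 1 of several arrays (highest adjusted p 0.349, 0.0984, 0.0939 and 0.112).

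Interferon-stimulated genes, which code for antiviral proteins, rose more in CAST than in the other strains. Of 20 measured, 17 exceeded the mean response of the other strains and 0 fell below it, also when adjusted over the list alone (median 1.499, adjusted p 1.4e-39, camera). Usp18, a brake on interferon signalling, rose by 5.31 in CAST and 1.06 elsewhere (difference 4.25, SE 0.31), and its other probes differed by 4.49 and 3.16. Ifit2 differed by 4.10 (SE 0.24, 1.82 on its other probe), the antiviral GTPase Mx1 by 3.87 (at least 11.1-fold higher after axotomy in CAST, and above background on 1 of 35 naive arrays), Ifit3 by 3.30, Bst2 by 2.92 and Oasl2 by 2.34. Ifi27l2a, an interferon-induced gene, differed by 3.25. In naive ganglia of CAST 6 members of the list were higher and 7 lower than in the other strains, with a median of −0.11 (adjusted p 0.765). Ifit2 was among the lower ones, at −2.43 on the reported probe and −3.85 on its other probe. On that other probe the larger response did not make up for the lower naive level. Genes of MHC and antigen presentation followed, with 10 of 18 above the others, 13 when adjusted over the list alone (median 0.84, adjusted p 1.2e-15), including H2-T23 (1.85), Cd74 (1.47) and B2m (1.08). Both lists held with an estimated correlation (adjusted p 3.0e-05 and 0.0007). Macrophage markers went both ways, with 6 of 19 above and 3 below, 8 and 3 when adjusted over the list alone (median 0.52, adjusted p 0.0207, adjusted p = 0.453 with an estimated correlation). Among them Fcer1g was at 2.65, the protease gene Ctss at 2.18 and Ly86 at −1.15. Fcer1g was above background in CAST and C57 alone, where it rose by 2.92 and 2.36. For Ly86 the mean of the other strains was raised by WSB (2.67), C3H (0.99) and AJ (0.82), where its naive level was lowest. The macrophage call was lost without CAST naive replicate 1 (adjusted p 0.0534) and without strain NOD (0.074) or NZO (0.154), and the median was −0.0833 when only probes detected on every array were used.

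**Figure D3:**
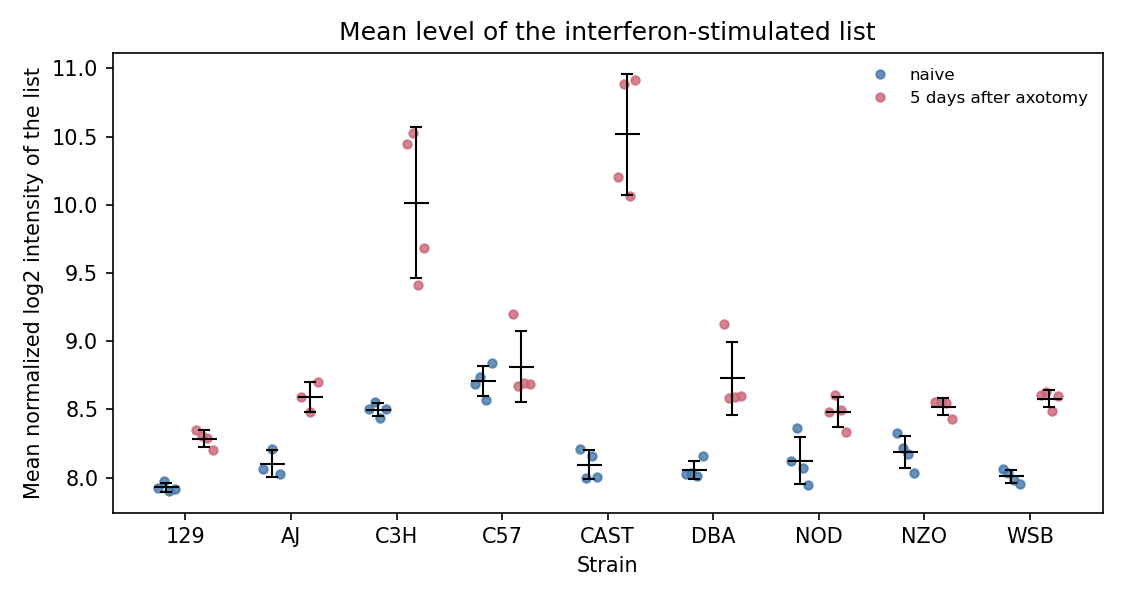
Mean level of the 20 measured interferon-stimulated genes (vertical axis, normalized log2 intensity) in each array (points) by strain (horizontal axis), naive in blue and 5 days after axotomy in red; bars show mean ± SD. CAST goes from 8.09 to 10.52 and C3H from 8.50 to 10.02.

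Among the remaining genes with a larger response in CAST were Klk4 (3.74, SE 0.12) and Ms4a8a (3.19). On the other side were Lipn (−4.62, SE 0.17), the carbonic anhydrase Car3 (−3.62, SE 0.63), the Langerhans cell lectin gene Cd207 (−2.72, −1.75 on its other probe), Hao1 (−2.62), Wfdc17 (−2.50), 5031410I06Rik (−2.45), Reg3b (−2.42) and Gpr151 (−2.33, from 3.44 in CAST and 5.78 elsewhere). Klk4, Ms4a8a, Lipn, Cd207, Hao1, 5031410I06Rik and Reg3b were not above background on any of 35 naive arrays and Wfdc17 on 5, so the size of their differences depends on where background lies. In CAST itself Hao1 responded by −0.14 and Wfdc17 by 0.08. For genes with a smaller response, a probe that binds CAST poorly would also give little or no rise there, which was not tested. Cholesterol synthesis genes were below the other strains in 5 of 16 members, 6 when adjusted over the list alone, and above in 0 (median −0.19, adjusted p 0.00114, held with an estimated correlation at 0.011), with Mvd at −0.83, Hsd17b7 at −0.44 and Fdps at −0.38. Regeneration-associated genes were below in 6 of 31 and above in 1, or 7 and 2 when adjusted over the list alone (median −0.11, adjusted p 0.0319, adjusted p = 0.404 with an estimated correlation). They include the adhesion molecule Chl1 (−1.58), Cckbr (−1.23) and the neuropeptide gene Nts (−1.22). That list's call was lost without CAST naive replicate 1 (adjusted p 0.149), replicate 2 (0.0568), CAST axotomy replicate 4 (0.0987) or AJ axotomy replicate 4 (0.0508), with the authors' matrix (0.108), and without strain 129 (0.0646), DBA (0.0838) or WSB (0.137).

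The response of Atf3 (−0.32, adjusted p 0.429), Jun (−0.16), Gap43 (0.06), Gal (0.31) and Npy (−0.23) in CAST did not pass a difference from the other strains. Gal after axotomy lay at 14.90 (CAST) to 15.06 (C57), while its naive levels ran from 9.66 (WSB) to 11.50 (C57). Its response thus varied mainly with the naive level, and an upper limit of the scale was not tested. Sprr1a was at −1.03 (adjusted p 0.0392), a call lost without any single one of 6 arrays (highest adjusted p 0.226), with array weights (0.139) and without runs 4 and 9 (−0.42, adjusted p 0.587). In total 506 genes were above and 442 below the other strains. Camera called 5 of 28 lists, 3 of which held with an estimated correlation, and fry called 7. Without CAST axotomy replicate 1 neutrophil markers were called as well (adjusted p 0.0239 against 0.166, median −0.84 with all arrays). Axon growth inhibition genes were called without CAST naive replicate 3 (adjusted p 0.0439 against 0.109, median 0.14 with all arrays) and without runs 4 and 9 (0.0487). Adipocyte genes (adjusted p 0.109, median −0.18) were called with median scaling (0.0417), without strain AJ (0.0495) and without runs 4 and 9 (0.0198).

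After axotomy the levels in CAST differed from the mean of the other strains in 5588 genes (47.3%), 3207 higher and 2381 lower. The highest were the taste receptor gene Tas1r1 (6.40, at least 48.4-fold), Fcer1g (5.63, above background in CAST and C57 alone), Mx2 (5.62), Eno1b (4.94), Tspan10 (4.66, at least 12.7-fold), the class I gene H2-D1 (4.40), the BMP receptor gene Bmpr2 (4.24) and Mx1 (4.06). The lowest were the pyruvate kinase gene Pkm (−8.48), Mrpl50 (−7.07, at least 70.7-fold), Lrpap1 (−6.93), Isca1 (−6.61, at least 75.0-fold), Plaa (−6.20, at least 50.7-fold), Brox (−6.15), Senp2 (−5.88) and Slc7a14 (−5.80, at least 40.0-fold). The other probes of Slc7a14 gave −5.51 and −0.91. Genes at least 4-fold lower in CAST numbered 293 and those at least 4-fold higher 90. For the lower genes a probe that binds CAST poorly could give such levels, and the sequences were not checked. Interferon-stimulated genes were higher in 19 of 20 (median 1.57, adjusted p 1.2e-10, adjusted p = 0.101 with an estimated correlation). Genes of MHC and antigen presentation were higher in 13 of 18 and lower in 3 (median 0.87, adjusted p 0.0171, adjusted p = 0.939 with an estimated correlation). Here H2-Ab1 was at −3.46 on its brightest probe and at 0.20, −2.57 and 0.91 on its others. Cholesterol synthesis genes were lower in 9 of 16 and higher in 3 (median −0.38, adjusted p 0.0171, adjusted p = 0.101 with an estimated correlation), with Stard4 at −4.80 (at least 20.2-fold), Pmvk at −3.91 and Lss at 1.55. That call was lost when only probes detected on every array were used (adjusted p 0.0842, camera). Poor binding to CAST was not tested for Stard4 and Pmvk either. Sprr1a was lower in CAST by −1.11 (adjusted p 6.2e-05), while Atf3 (−0.01), Jun (0.08), Gap43 (0.16), Gal (−0.10) and Npy (0.44, adjusted p 0.0714) did not pass. Camera called 3 lists, fry 18.

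Naive ganglia of CAST differed from the mean of the other strains in 5323 genes (45.1%), 3074 higher and 2249 lower. Highest were Tas1r1 (6.42, at least 49.6-fold), Eno1b (5.12), Tspan10 (4.62, at least 12.2-fold), the claudin gene Cldn14 (4.26), Mx2 (4.11), Bmpr2 (4.00, 4.31 on its other probe), Bglap (3.99) and the nicotinic receptor subunit Chrna3 (3.93). Lowest were Pkm (−8.22), Mrpl50 (−6.61, at least 63.1-fold), Lrpap1 (−6.57), Isca1 (−6.49), Plaa (−5.82), Senp2 (−5.71), Slc7a14 (−5.66) and Brox (−5.64). Among the fixed genes, Jun (0.24) was higher in CAST. Npy (0.67) was also higher, a call lost without CAST naive replicate 1 or 2 (highest adjusted p 0.267), and Gal (−0.41, adjusted p 0.0447) was lower, a call lost without any single one of 9 arrays (highest adjusted p 0.64). Atf3 (0.30, adjusted p 0.08), Gap43 (0.10) and Sprr1a (−0.08) did not pass. Smad2 (0.21) and Acvr2b (0.26) passed, each lost without 1 of the CAST naive arrays (highest adjusted p 0.0504 and 0.106), and Acvr2b also with median scaling (0.122). Genes at least 4-fold lower in CAST numbered 280 and those at least 4-fold higher 61. For 67 of the 280 a further probe was measured, and the median difference over 103 such probes was −0.10, where the reported probes gave −3.04. Camera called 0 lists here, 0 at an unadjusted p below 0.05 and 0 with an estimated correlation, while fry called 16.

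**Figure D4:**
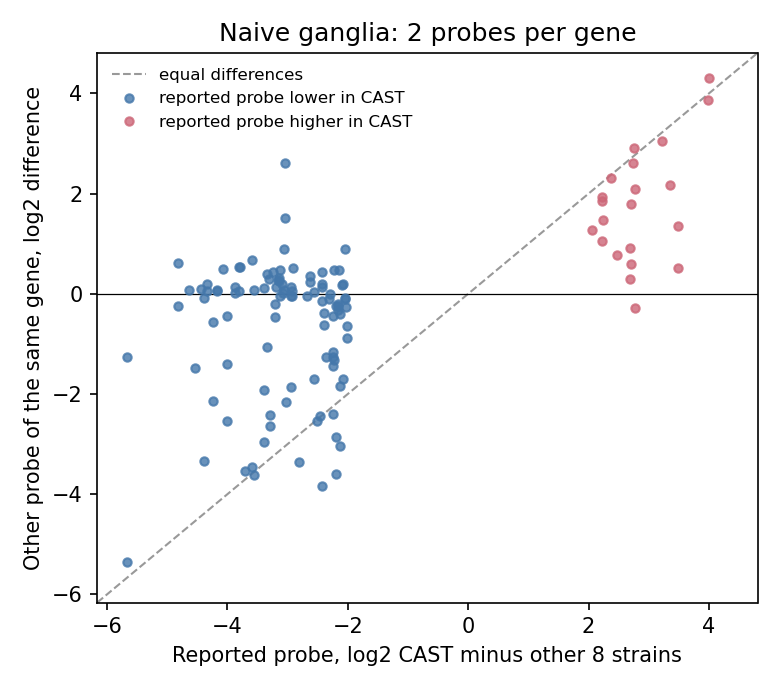
Genes more than 4-fold lower (blue) or higher (red) in naive CAST ganglia: log2 difference of the reported probe (horizontal axis) against that of each other probe of the same gene (vertical axis). For the lower genes the other probes have a median of −0.10, where the reported probes have −3.04; the dashed line marks equal differences.

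Among naive ganglia of all strains, 7015 genes (59.4%) differed in the F-test. Sspn, a membrane protein gene of the dystrophin complex, was at 11.2 to 11.4 in 129, AJ, C57 and WSB and at 4.79 to 5.09 in the other 5 strains. Thumpd1 was at 10.6 to 10.8 in 129, C57, CAST, NOD and WSB and at 4.88 to 5.07 in AJ, C3H, DBA and NZO. Isca1 was at 5.86 in CAST and 12.2 to 12.6 elsewhere, Pkm at 5.97 against 13.6 to 14.6, and Mrpl50 at 5.36 against 11.8 to 12.04. For each of these genes a probe that binds some strains poorly could give such levels, and the sequences were not checked.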

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

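In this part the tests on other probes, within runs, without single CAST arrays, on macrophage markers and of CAST against C57 were chosen after the results they bear on had been seen, while the test of the normalization and the splits of the arrays were set before.

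In naive ganglia, genes at least 4-fold lower in CAST outnumbered those at least 4-fold higher by 280 to 61 (82.1% lower), against 19.1% (C57) to 75.9% (WSB) lower in the same comparison of each other strain. Quantile normalization as the cause is excluded by the share under median scaling, 82.5%. Sequence differences between CAST and the probes may account for many of these genes: other probes of the same genes showed a median 0.0451 of the reported difference (interval −0.0112 to 0.134), against 0.652 for the genes higher in CAST and 0.66 and 0.919 for genes that rose or fell after axotomy. In CAST 68 genes were not above background on any array while detected on every array of the other strains, against 0 to 5 in each other strain. Real strain differences stay open for each gene, above all where a single probe was measured, and the sequences themselves were not checked.

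Interferon-stimulated genes had a median response 1.499 larger in CAST than in the other strains. Column runs as the whole cause are excluded, since within runs the difference between CAST and the other strains grew by 1.82 from naive to axotomy (SE 0.36), with 1.04 to 2.43 after axotomy and −0.28 to 0.05 in naive ganglia. A single CAST array as the source is excluded by a lowest median of 1.41 without any one of them (largest adjusted p 1.9e-34), although only 3 of the 4 CAST rises lay above the highest of 31 arrays of the other strains (1.97 to 2.82, against −0.04 to 2.03). More macrophages would raise their markers about alike, but the 19 markers, all detected on every CAST axotomy array, had a median of 0.515 (interval −0.0833 to 0.692). This lies below the interferon median, which argues against that as the whole cause. The markers ran from −1.15 (Ly86) to 2.65 (Fcer1g), but both ends depend on the signal of other strains. Fcer1g was above background in CAST and C57 alone. Ly86 responded by −0.78 in CAST and −0.70 in 129, and rose only in WSB, C3H and AJ, where its naive level was lowest. A stronger interferon response of the strain may underlie the pattern as a hypothesis, and other causes were not tested and stay open.

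Inhba rose by 2.52 more in CAST than in the other strains. No run held both naive and axotomy arrays of CAST. Within runs, CAST minus the other strains was at least 2.50 after axotomy and at most 1.14 in naive ganglia. The mean of these differences grew by 2.43 (SE 0.32) from naive to axotomy, which excludes column runs as the whole cause. A probe that binds the other strains poorly would not be expected to read low in C57, the strain of the mouse reference genome, and CAST exceeded C57 after axotomy by 3.46, which argues against that explanation. A strain difference in the injury response of Inhba may be at work, as a hypothesis found and examined on the same data. How much of the size is due to the weak signal of the other strains stays open, since without background correction the difference was 1.301.

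The response differed between strains in 1915 genes, and median scaling lowered the count to 1224. The highest of the other splits of the arrays, among 100 drawn with the real one, gave 9. These splits exchanged strain labels within a treatment, so level differences between strains widened the spread within the drawn groups. Low counts follow from that whether or not responses differ, so the splits cannot decide on chance here. The difference of CAST from the other 8 strains in 948 genes stands against a highest other split of 53, with the same limit. The same test of each remaining strain gave 418 genes for 129, 165 for AJ, 131 for C3H, 141 for C57, 294 for DBA, 107 for NOD, 305 for NZO and 811 for WSB, with no splits drawn for these.

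For 2 other counts chance is excluded, each the highest of 100 splits. These are the mean over strains (7291 genes, highest other split 48) and strain differences in naive ganglia (7015, 37). The counts for CAST after axotomy (5588, 2127) and in naive ganglia (5323, 46) were also the highest of 100. Their splits again exchanged strain labels within a treatment, so level differences among the other strains widened the drawn groups. They cannot decide on chance for CAST. Each strain with 8 arrays has 35 splits, and the real one gave the most genes: 3756 in 129 (highest other 1372), 3211 in C3H (1092), 2795 in C57 (721), 3608 in CAST (1159), 3955 in DBA (1323), 2939 in NOD (874), 3240 in NZO (760) and 4443 in WSB (1848). Ranking first of 35 is a share below 0.05 in each of these strains, and the smallest that the splits allow. The 6 arrays of AJ allow 10 splits, too few for a share below 0.05, and the real split gave 2270 genes against a highest other of 2.

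Single genes whose response in CAST differed from the mean of the other strains by limma's test of the difference were, above it, Usp18 (4.25), Ifit2 (4.10), Mx1 (3.87), Klk4 (3.74), Ifit3 (3.30), Ifi27l2a (3.25), Ms4a8a (3.19), Bst2 (2.92), Fcer1g (2.65), Oasl2 (2.34), Ctss (2.18), H2-T23 (1.85), Cd74 (1.47) and B2m (1.08). Below it were Lipn (−4.62), Car3 (−3.62), Cd207 (−2.72), Hao1 (−2.62), Wfdc17 (−2.50), 5031410I06Rik (−2.45), Reg3b (−2.42), Gpr151 (−2.33), Fst (−2.12), Chl1 (−1.58), Acvr1c (−1.30), Cckbr (−1.23), Nts (−1.22), Ly86 (−1.15), Sprr1a (−1.03), Mvd (−0.83), Hsd17b7 (−0.44) and Fdps (−0.38). The sizes for genes at background in naive ganglia, such as Lipn, Klk4, Ms4a8a and Acvr1c, depend on where background lies. For genes below the other strains, such as Lipn, a probe that binds CAST poorly would also give a smaller response, which was not tested. Lists whose response differed by camera were MHC and antigen presentation (median 0.844), cholesterol synthesis (−0.187), macrophages (0.515, adjusted p = 0.453 with an estimated correlation) and regeneration-associated genes (−0.11, adjusted p = 0.404 with an estimated correlation), besides the interferon list.

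Of 48 tests for 1 array apart from the rest of its group (3 measures in 16 groups of 4), 5 found one, where chance gives about 1 in 20. For the mean of the interferon list these were C57 axotomy replicate 4 (9.20), DBA axotomy replicate 3 (9.13), NZO axotomy replicate 4 (8.43) and DBA naive replicate 4 (8.16), and for Inhba it was DBA naive replicate 2 (5.74).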

How the results depend on the processing

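The runs of 8 columns as a block and the fit without runs 4 and 9 were chosen after the data were seen, and the planned slide block was not run, since the files name no slides. Outside the leave-one-out fits, 304 recomputed main counts and values stayed within their limits and 25 did not. Named genes kept their side of the threshold in 6620 recomputations, while 120 lost a call, 47 gained one and 1 reversed with a call; for lists the numbers were 1700, 22, 48 and 3. Over genes and lists, leave-one-out fits included, 238 values not past the threshold changed sign and count as kept. Scaling by the median moved the median of all genes by less than 0.1. The mean correlation between strain responses, 0.79, became 0.838 with the authors' matrix and also without background correction. Among 408 called gene results the log2 differences without background correction were a median 0.741 of those reported (0.251 to 2.21), and 6 calls were lost. The size of differences thus depends on the background correction. With median scaling 1224 genes differed in the interaction F-test; the cause was not tested. Requiring a fold of at least 1.5 removes smaller changes by construction and left 1535 genes for the mean over strains, 1850 in 129, 1304 in AJ, 1627 in C3H, 1329 in C57, 1907 in CAST, 2134 in DBA, 1451 in NOD, 1587 in NZO, 2495 in WSB, 594 for the response of CAST, 2533 for CAST after axotomy and 2339 in naive ganglia. With only probes detected on every array, fewer genes were tested: 543 genes and 3 lists were called for the response of CAST, the macrophage list had a median of −0.0833, and H2-Ab1 after axotomy was at 0.91 in CAST, as another probe of the gene was chosen. Camera with an estimated correlation called 8 lists for the mean over strains, 3 for the response of CAST and 0 after axotomy, and fry 24, 7 and 18, and 16 in naive ganglia. Where fry called a list, its direction was opposite to camera's for TGF-beta and BMP signalling (mean over strains, median −0.22) and for endothelium and pericytes (after axotomy, median 0.16); the cause was not tested. Replicate numbers did not pair samples: the residuals of naive and axotomy arrays of the same strain and number correlated above 0.1 in 11 of 34 pairs (mean 0.03). A block of strain and number left 1382 genes in AJ, where it keeps only 2 pairs of arrays, and gave 7156 genes for the mean over strains (7033 shared) and 882 for the response of CAST (841 shared). With runs as a block these were 7312 (6849 shared) and 981 (819 shared), and no list call changed. Leaving out 1 array gave 7184 to 7354 genes for the mean over strains, 770 to 1005 for the response of CAST, 4961 to 5622 for CAST after axotomy, 4712 to 5368 in naive ganglia, 1770 to 2031 for the interaction, and 3 (without CAST naive replicate 1) to 6 lists (without CAST axotomy replicate 1 or CAST naive replicate 3) for the response of CAST. The response difference of Inhba passed under the 17 alternatives recomputed for it, at 1.29 to 2.77, and at 2.34 to 2.75 without any single array; it was not among the probes detected on every array and was not recomputed with all probes.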

Other observations

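The tests of lists for single strains and the single genes of other strains were chosen after values had been seen. Strains other than CAST also had responses of their own, tested against the mean of the other 8 strains with camera. In NZO macrophage markers responded less, with 12 of 19 lower (median −0.88, adjusted p = 2.8e-06 with an estimated correlation). In WSB they responded more, with 12 higher and 1 lower (median 0.81, adjusted p = 0.000212 with an estimated correlation). Cholesterol synthesis genes were above the other strains in WSB as well, in 8 of 16 members (median 0.25, adjusted p = 4.4e-05 with an estimated correlation). C3H shared the direction of CAST for interferon-stimulated genes, with 8 of 20 above the others (median 0.75, adjusted p = 0.00121 with an estimated correlation), among them Irf7 (2.11), and outside the list the chemokine gene Cxcl10 (2.31). C57 went the other way, with 8 of 20 below (median −0.70, adjusted p = 0.005 with an estimated correlation), including Usp18 (−1.67) and Igtp (−1.39). It started from the highest naive level, a list mean of 8.71 against 7.93 (129) to 8.50 (C3H), with 11 of 20 genes higher and 0 lower than in the other strains (median 0.39, adjusted p = 0.205 with an estimated correlation). After axotomy the C57 mean was 8.81, above every strain but CAST and C3H. Replicate 4 after axotomy lay 0.49 above the naive C57 mean, and the other 3 arrays between −0.04 and −0.02.

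Before injury, cholesterol synthesis genes were higher in C57 than in the other strains in 11 of 16 members (median 0.34, adjusted p = 8.3e-05 with an estimated correlation) and lower in C3H in 9 of 16 (median −0.28, adjusted p = 0.0014 with an estimated correlation). Wt1, a zinc-finger transcription factor gene, responded more in 129 (difference 2.59) and less in C57 (−2.13). The synaptic protein gene C1ql2 did the same, with 1.60 in 129 and −3.04 in C57. In DBA the carbonic anhydrase gene Car4 (3.09), the transcription factor gene Lmx1a (2.73) and Gdnf, a growth factor gene for neurons (2.65), responded more than in the other strains. The sizes depend on where background lies, since Irf7 and Lmx1a were not above it on any of 35 naive arrays, Gdnf on 1, C1ql2 on 2, and Wt1 on none of 129 or C57.

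Uts2b, a urotensin-related peptide gene, Chrna3 and the position gene Hoxd10 rose after axotomy in AJ, by 4.57, 2.88 and 1.97. In DBA Uts2b fell at least 16.7-fold and Chrna3 at least 2.56-fold, to levels not above background, and Hoxd10 changed by −2.30. A candidate explanation is that naive and axotomy samples of these strains held ganglia of different spinal levels. It predicts that the other Hox genes of paralogous groups 10 to 13 differ in response between AJ and DBA by more than 0.5. The mean of the 5 measured genes was −0.01 in AJ (SE 0.11) and −0.07 in DBA (SE 0.10), a difference of 0.0617 (SE 0.15), but the members went different ways. Hoxc10, the brightest of them, was at −0.43 in DBA (adjusted p 0.00348) and −0.09 in AJ, and Hoxa10, not above background in DBA after axotomy, fell there at least 1.14-fold (adjusted p 0.0204). The 20 measured genes of groups 1 to 9 differed by −0.15 (SE 0.06). Uts2b, Chrna3 and Hoxd10 also varied together between arrays of the same group, with Pearson correlations of 0.66 to 0.75 over 70 arrays. Without the 2 farthest arrays these were 0.56 to 0.66. Their spread was widest in 129 after axotomy, where Uts2b ran from 4.83 to 9.01 and Hoxd10 from 8.30 to 11.16. These genes thus varied between samples of a single strain and treatment as well. The question of spinal levels stays undecided, since most genes of groups 10 to 13 lay near background. The labels do not name the spinal levels.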
